A study of Homo sapiens with 12 samples.

How the data were processed

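RNA from LUHMES cells, a human fetal midbrain line, was sequenced as poly-A RNA on an MGI DNBSEQ-T7 instrument, per the labels' protocols. The labels give 12 samples in 6 groups of 2: control, 1 µM and 10 µM lead(II) acetate, each at 3 h and at 24 h. The same labels number the replicates 1 and 2 in each group, without saying what the numbers share. The cells were moved to new plates 1 h before exposure, so the time comparison of the controls also covers the time after replating. Salmon and the hg38 build are named in the submitters' processing notes, without versions or roles, and the annotation and any further steps are not given in the sources used here.

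The authors deposited a table of estimated counts per gene, with values that are not whole and column totals from 16348501 to 18155684 (median 17146413). They also deposited a table of normalized log2 values in which each gene's median over the 12 libraries is 0, and per the file headers each of its columns pairs a condition with a library name. How the libraries were scaled, and any pseudocount, is not given in the sources used here. Over 176 genes the ranges of the normalized values were 0.883 times those of the log2 counts, so the values were read as log2 and a difference is on the authors' scale, which can understate the change of genes with low counts. The mitochondrially encoded genes had no row among the normalized values, and HSPA1A and TH did not reach the count minimum, so these were not tested. The share of counts in 25 rows whose gene name had become a date was 0.171%, and they matched no gene of the normalized table. No 2 libraries held identical values.

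The tables conflict over which library a name stands for. Over 10076 genes only 1 of 12 count columns correlated best with the normalized column of its own name, and 12 of 12 correlated best with the name at their place in alphabetical order. The conflict was seen before any group was compared. Columns were never reassigned by their values. The normalized table, whose headers state the condition, was used for every main comparison. The count table served there only for mean counts over all libraries, the scale check and depth, and comparisons under its own names were made only as alternatives. This changed the main test from edgeR's quasi-likelihood test, as planned for counts, to limma. Depth is therefore given as a range over columns and not per group. Depth limits genes with few counts most, and a filter removed genes under a mean of 10 estimated counts, which left 12603.

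Symbols were matched exactly between the tables. From the normalized values, 154 rows sharing a symbol with another row were left out, which left 20600 genes with a value and a unique symbol, and 18343 of them matched the count table. Limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group to the 12 libraries, with a trend of the variance on the log2 mean count and robust moderation. Two-sided p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The 11 comparisons were each dose against control at each time, both doses together, 10 against 1 µM, the difference of each dose's effect between times, and control at 24 h against control at 3 h. The sets of 28 gene lists, their members, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, which asks whether a list's own genes move one way. Adjustment was over the 25 lists tested, while lists chosen after the main results were adjusted only among themselves. With the estimated correlation no list passed in any comparison. The lowest such adjusted p over control time was 0.158, although limma called 5875 genes there. Failing this version of camera therefore does not show that a list was unchanged. For the correlation between doses, 100 simulations drew unchanged groups that share the control libraries. They drew genes independently, each with 1 spread for all 6 groups, so their values and ranges are a rough guide. The procedure was tested on simulated data for 10 µM against control at 24 h with 12603 genes. It called 57.6% of genes changed by 0.5, 86.3% of those changed by 1 and 94.2% of those changed by 2 on the log2 scale. Of its calls 4.92% were false. The simulated genes were independent, with each gene's residual spread and no effects of single libraries. These shares may therefore not hold in the real data.

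Named genes were up to 10 per direction with the largest difference among those past the threshold whose libraries did not overlap between groups and which had a mean CPM of at least 1. Where fewer than 5 passed, the 5 with the smallest p were taken, together with up to 4 members of each list with the smallest p, and a fixed panel of genes in the 4 comparisons of a dose with its control. HARS2, RPN1, MAGT1 and 7 further lists were chosen after the main results were seen. Of the 28 lists, 3 had fewer than 5 measured members, and the mitochondrially encoded one had 0. Metallothionein, ribosomal protein and histone genes have near-identical copies and are uncertain.

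The alternatives were no filter on low counts, a minimum of 50 counts, a fit of only the groups compared, the replicate number as a block, each library left out in turn, the estimated correlation and fry. Added after seeing the data were splitting the controls between the doses for their correlation, centring each library on its median, removing each library's trend with mean count, and edgeR 4.0.16 with TMM factors on the count table under its own column names. The planned runs of edgeR with RLE and upper-quartile factors and of DESeq2 1.42.0 were made on that table only for numbers of genes called, since its names conflict. The estimated counts were rounded to whole numbers for these runs. If the normalized names are right, groups under the count names hold libraries of the wrong time, and these runs do not test the comparisons named. Gene positions came from GENCODE version 29 on GRCh38. Single-gene results of 2 members of the cholesterol list are not reported here.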

Results

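RNA was measured in LUHMES cells, a human fetal midbrain line held in division by a conditional oncogene and turned into neurons when that oncogene is switched off with tetracycline. The cells were on day 2 of differentiation when they were moved to coated plates. They then received lead(II) acetate, a soluble lead salt, at 1 or 10 µM or no lead, for 3 or 24 h. Poly-A RNA was sequenced from 12 libraries, which form 6 groups of 2. Column totals of the count table ran from 16348501 to 18155684 estimated counts, with a median of 17146413. The group comparisons used the deposited normalized log2 values of 12603 genes, except where another filter or the count table is named. Differences are given as log2 differences ± SE with n = 2 libraries per group. In a comparison of lead with control, rose and fell mean higher and lower than in the controls of the same time. No label says that the libraries of a group came from separate cultures. Each single-gene p-value therefore measures only the spread between these samples, which may be technical. Camera's p-values at the preset correlation compare a list's genes with all other genes. They do not measure how much a list's median varied between the libraries.

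Time parted the libraries more than lead did. The first principal component held 71.1% of the variance and separated all 3 h libraries from all 24 h libraries. The second held 7.70% and followed lead at 24 h. The 24 h controls lay at 15.49 and 14.01 on it, the 24 h libraries with 10 µM at -10.37 and -16.49. At 3 h the 10 µM libraries lay apart from each other on this component, at 1.67 and -18.0. The third held 4.92%, and the first replicate of the 3 h control stood alone on it at 23.0.

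The comparison of 10 µM lead with control at 24 h asked which genes differed after the longer exposure to the higher dose. Genes of the response driven by the transcription factors ATF4 and CHOP rose. The cystine importer gene SLC7A11 rose by 2.53 ± 0.41 (adjusted p = 0.0292) and the leucine transporter gene SLC7A5 by 2.09 ± 0.30 (adjusted p = 0.0244). PHGDH, the first enzyme of serine synthesis, rose by 1.78 ± 0.26 (adjusted p = 0.0275), and the transcription factor ATF5 by 1.51 ± 0.21 (adjusted p = 0.0200). The largest rise past the threshold was that of STC2, a secreted glycoprotein gene, at 2.94 ± 0.47 or 7.70-fold (adjusted p = 0.0310), with 2.32 without the second 10 µM library and 3.57 without the first. GARS, the glycyl-tRNA synthetase gene, rose by 0.72 ± 0.11 (adjusted p = 0.0215). Of the 40 measured genes of the ATF4 and CHOP list, all 40 were higher, 20 passed the test over all genes and 35 passed when adjusted over the list alone. The list's median was 0.81, and camera's adjusted p was 1.61e-35 with a preset correlation and 0.317 with an estimated correlation. ATF4 itself was at 0.54 ± 0.15 (adjusted p = 0.147) and DDIT3, which encodes CHOP, at 2.33 ± 0.59 (adjusted p = 0.128), so neither passed. The list's median was 0.66 in the first 10 µM replicate and 1.01 in the second.

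Chaperones of the endoplasmic reticulum (ER) were higher as a group. HSP90B1, the ER form of HSP90, rose by 2.11 ± 0.35 (adjusted p = 0.0420). The disulfide isomerase gene PDIA6 rose by 1.97 ± 0.35 (adjusted p = 0.0497). CANX, a chaperone of glycoproteins, rose by 1.39 ± 0.22 (adjusted p = 0.0310), and SPCS2, a subunit of the signal peptidase, by 0.81 ± 0.12 (adjusted p = 0.0215). HSPA5, the main ER chaperone of the HSP70 family, was at 2.26 ± 0.46 (adjusted p = 0.0704). All 41 genes of the ER chaperone and unfolded protein list were measured and 40 were higher, with a median of 1.12. Over all genes 4 passed, and adjusted over the list alone 32 passed upward and 1 downward. Camera's adjusted p was 3.91e-24, against 0.317 with an estimated correlation. ER stress is a theme the submitters name for these samples, so this list is not independent evidence of its direction.

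**Figure D1:**
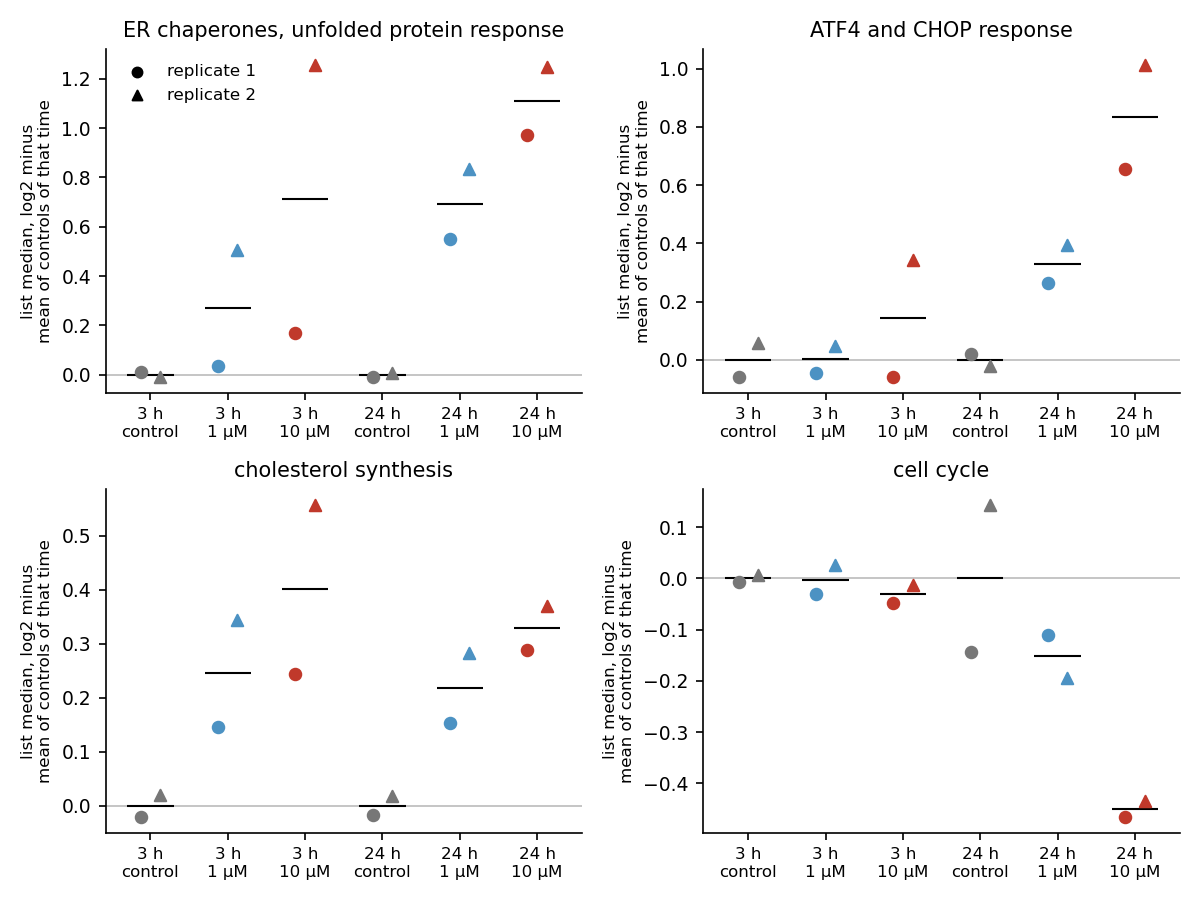
Median log2 level of 4 gene lists in each library, minus the mean of the controls of the same time. Circles are replicate 1, triangles replicate 2, and bars the mean of the 2 libraries. The ER list stood at 0.17 and 1.26 in the 10 µM libraries at 3 h, and at 0.97 and 1.25 at 24 h.

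Genes that handle zinc and other metals were higher in part. SLC30A1, which exports zinc from the cell, rose by 0.78 ± 0.10 (adjusted p = 0.0132). It was the only gene of the 31 measured on the zinc, copper and iron list to pass over all genes, and 2 passed when adjusted over the list alone. That list had a median of 0.06, or 0.09 without the first 10 µM library, and camera's adjusted p was 0.00977, or 0.317 with an estimated correlation. All 4 measured metallothioneins, small metal-binding proteins, were higher, with a median of 1.45. This was too few for a list test, but all 4 passed when adjusted over the list alone. Their values are uncertain because these genes are near-identical copies that share reads. MT1E passed over all genes at 1.93 ± 0.35 (adjusted p = 0.0420), with a mean of only 13.3 counts. MT1F was at 1.69 ± 0.34 (adjusted p = 0.0635), MT2A 2.30-fold higher with a log2 SE of 0.42 (adjusted p = 0.250) and MT1X at 0.92 ± 0.26 (adjusted p = 0.161). In the 24 h libraries with 10 µM, MT1E stood at -0.00573 and 0.386, against 0.266 and 0.840 in the 3 h controls. MT1X stood at 0.0148 and 0.0769, against 0.0182 and 0.179. These 2 genes thus lay near or below their 3 h level. MT1F (1.59 and 1.61, against -0.745 and -0.371) and MT2A (0.482 and 0.248, against -0.537 and -0.401) lay above theirs.

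Antioxidant genes under the transcription factor NRF2 were also higher than in the 24 h controls. NQO1, a quinone reductase, rose by 1.51 ± 0.20 (adjusted p = 0.0168). PIR, an iron-binding nuclear protein, rose by 1.56 ± 0.30 (adjusted p = 0.0481), and ME1, which makes NADPH, by 1.28 ± 0.22 (adjusted p = 0.0366). In the 24 h libraries with 10 µM, NQO1 stood at -0.00424 and 0.217, ME1 at -0.0471 and 0.0939 and PIR at 0.354 and 0.461. In the 3 h controls NQO1 stood at 0.00424 and 0.0307, ME1 at 0.0471 and 0.201 and PIR at 0.156 and 0.352. NQO1 and ME1 thus lay near their 3 h level. Heme oxygenase, HMOX1, was at 1.11 ± 0.36 (adjusted p = 0.220). Of the 30 measured NRF2 genes 27 were higher, 4 passed over all genes, among them SLC7A11, and 10 passed when adjusted over the list alone. The median was 0.22, with an adjusted p of 2.03e-09 by camera and 0.317 with an estimated correlation. All 25 cholesterol synthesis genes were higher, with a median of 0.34 and an adjusted p of 2.43e-13, or 0.317 with an estimated correlation. The sterol oxidase MSMO1 passed, at 0.55 ± 0.10 (adjusted p = 0.0423), and 15 genes passed when adjusted over the list alone.

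Genes of cell division fell. TOP2A, the topoisomerase of dividing cells, was at -1.46 ± 0.18 (adjusted p = 0.0132). AURKB, a mitotic kinase, was at -1.55 ± 0.21 (adjusted p = 0.0161), and CDC20, an activator of the anaphase-promoting complex, at -1.04 ± 0.10 (adjusted p = 0.0130). The kinesin gene KIF2C was at -1.48 ± 0.17 and the separase gene ESPL1 at -1.68 ± 0.19 (adjusted p = 0.0132 for both). NEIL3, a DNA glycosylase, showed the largest fall at -2.32 ± 0.28 (adjusted p = 0.0132). Of the 36 cell cycle genes 35 were lower, 13 passed over all genes and 28 passed when adjusted over the list alone. The median was -0.57, with an adjusted p of 7.02e-26 by camera and 0.317 with an estimated correlation. The median was -0.30 without the second 24 h control and -0.77 without the first. Outside that list, LFNG, a glycosyltransferase that modifies Notch receptors, fell, at -1.66 ± 0.20 (adjusted p = 0.0132), as did the cyclin gene CCND1, at -1.45 ± 0.24 (adjusted p = 0.0335).

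**Figure D2:**
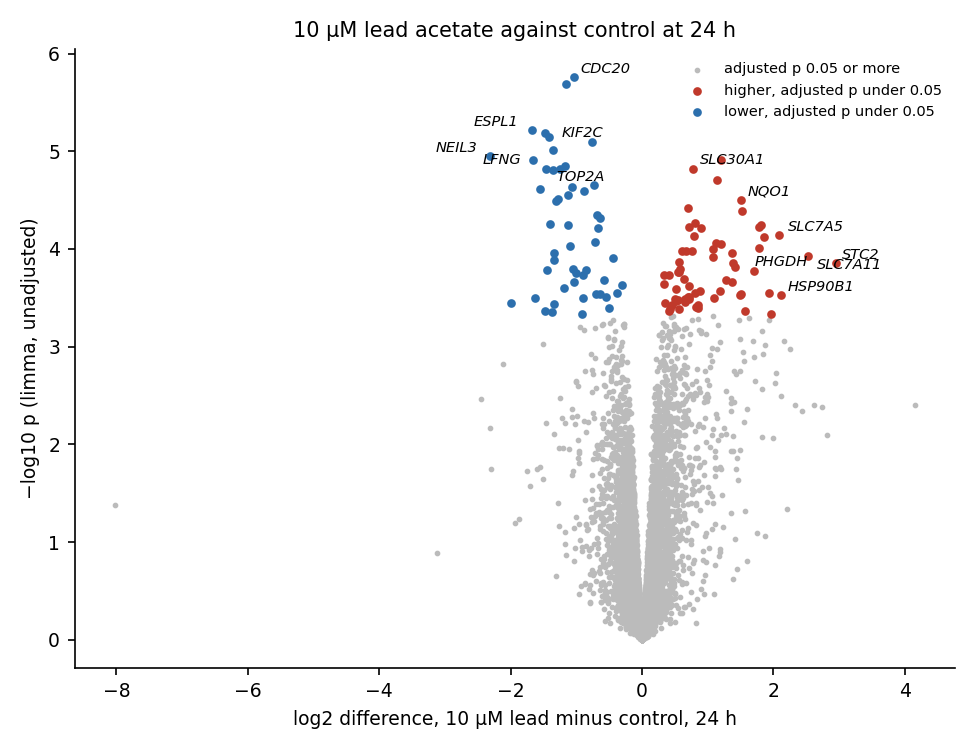
Log2 difference of each of 12603 genes between 10 µM lead and control at 24 h (horizontal axis) against the negative log10 of limma's unadjusted p (vertical axis). Coloured points are the 66 higher and 51 lower genes past the threshold. CDC20 and KIF2C lie high on the left, and SLC30A1 and NQO1 high on the right.

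In all, limma called 66 genes higher and 51 lower at 10 µM and 24 h, of 12603 tested. An unadjusted p under 0.05 was seen for 1642, where chance gives 630.2 on average. That number is a rough guide only. It was not reached at 1 µM and 3 h (476) or between doses at 3 h (216) and 24 h (557), but was exceeded in the other comparisons. Of the 66 higher genes 34 were on a list fixed beforehand, and of the 51 lower genes 13 were. All 117 called genes kept their sign with each of the 12 libraries left out in turn. The number called depended on single libraries, at 0 without the second 24 h control and 23 without the first. It was 29 without the second 10 µM library at 24 h. Leaving out libraries of the 3 h groups, which enter only through the shared spread, gave 34 without either 1 µM library, 73 without either control and 319 without either 10 µM library. The number was 30 with no filter on low counts, 371 in a fit of the 2 groups alone and 299 with the replicate number as a block. The balance of directions changed too, with 7 higher and 23 lower without the filter and 280 higher and 91 lower in the 2 groups alone. On the count table, whose column names conflict with the normalized table, edgeR called 0 genes and DESeq2 17. If the normalized names are right, each control group under the count names joins a 3 h and a 24 h library. Each dose group then holds libraries of the other time. In that case the counts of genes called on that table, here and below, do not test the comparison named.

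The remaining lists with enough members for a list test moved little after 10 µM lead at 24 h. Of the 80 genes of nuclear-encoded oxidative phosphorylation none passed, and the median was -0.04 (camera adjusted p = 0.124). This respiration theme is also named by the submitters, as is the ribosome. Cytosolic ribosomal protein genes, uncertain because of their many copies, had a median of 0.07 over 78 genes (adjusted p = 5.05e-04, or 0.756 with an estimated correlation). None passed singly, and that median was 0.02 without either the first 24 h control or the second 10 µM library and 0.12 without the second 24 h control. Proteasome subunits were at -0.06 (adjusted p = 0.0381, or 0.658 with an estimated correlation), and at -0.02 without the second 24 h control. That call ended in a fit of only the groups compared and with each library's trend with mean count removed. Mitochondrial ribosomal proteins were at -0.04 (adjusted p = 0.124), heat shock genes at -0.05 (adjusted p = 0.124) and neural progenitor genes at -0.06 (adjusted p = 0.0540). The progenitor filament gene NES was at -0.54 ± 0.12 (adjusted p = 0.0838). Heme synthesis genes had a median of -0.08 and a mean of 0.02 (adjusted p = 0.961). FECH, which inserts iron into protoporphyrin to form heme, was at 0.43 ± 0.09 (adjusted p = 0.0599).

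Neuronal lists did not pass at 10 µM and 24 h. Dopaminergic genes had a median of 0.03 (adjusted p = 0.830), and GCH1, which makes the cofactor of dopamine synthesis, was at 1.71 ± 0.38 (adjusted p = 0.0794). Cytoskeleton and growth cone genes were at -0.02 (adjusted p = 0.830), synaptic genes at -0.03 (adjusted p = 0.660), and glutamate receptor and calcium genes at -0.06 (adjusted p = 0.279). Immediate early genes were at 0.03 with a mean of -0.03 (adjusted p = 0.775), and p53 targets at 0.02 (adjusted p = 0.303). One p53 target, PMAIP1, which promotes cell death, rose by 1.504 ± 0.267 (adjusted p = 0.0420). Lysosome and autophagy genes were at 0.03 (adjusted p = 0.124). On that list the cholesterol carrier NPC2 rose by 1.12 ± 0.17 (adjusted p = 0.0265) and GABARAPL1, an autophagosome protein, by 0.71 ± 0.13 (adjusted p = 0.0395). Glycolysis and hypoxia genes had a median of -0.06 and a mean of 0.01 (adjusted p = 0.334), while the growth factor VEGFA rose by 1.08 ± 0.17 (adjusted p = 0.0275). Inflammatory and interferon genes were at 0.09 (adjusted p = 0.349), and histone genes, which are near-identical copies, at -0.03 (adjusted p = 0.830). Markers of astrocytes and oligodendrocytes were at -0.10 (adjusted p = 0.658) and of fibroblasts at -0.07 (adjusted p = 0.658). Only 2 microglia markers were measured, with a median of 0.72 and no list test.

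At 1 µM and 24 h 6 lists passed, each also past the threshold at 10 µM, and no single gene passed. The zinc, copper and iron list, at 0.05 (adjusted p = 0.0552), and the proteasome list, at -0.03 (adjusted p = 0.256), did not pass at this dose. The ER list rose, with 40 of 41 genes higher and a median of 0.69 (adjusted p = 4.36e-24, or 0.575 with an estimated correlation). HSP90B1 was at 1.70 ± 0.35 and CANX at 1.05 ± 0.22, both with an adjusted p of 0.884. Adjusted over the list alone 18 of these genes passed. The ATF4 and CHOP list was higher in 39 of 40 genes with a median of 0.32 (adjusted p = 2.24e-18, or 0.575 with an estimated correlation), and none passed when adjusted over the list alone. Cholesterol synthesis genes were higher in 24 of 25, with a median of 0.22 (adjusted p = 1.22e-11, or 0.575 with an estimated correlation). SLC30A1 was at 0.53 ± 0.10 (adjusted p = 0.884).

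The cell cycle list was lower at 1 µM and 24 h, with a median of -0.14 (adjusted p = 4.71e-06, or 0.799 with an estimated correlation), but -0.02 without the second 24 h control and -0.29 without the first. NRF2 genes had a median of 0.08 (adjusted p = 0.00358, or 0.799 with an estimated correlation). That call ended without the first 24 h control, at 0.05, and without the second 1 µM library. Ribosomal protein genes were at 0.05 (adjusted p = 0.00185, or 0.799 with an estimated correlation), at -0.03 without the second 1 µM library, 0.13 without the first and 0.00 without the first 24 h control. Metallothioneins had a median of 0.80, and 2 of 4 passed when adjusted over the list alone. No gene passed limma (0 called), with 679 at an unadjusted p under 0.05. On the count table as named, with its conflicting column names, edgeR called 0 and DESeq2 15.

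**Figure D3:**
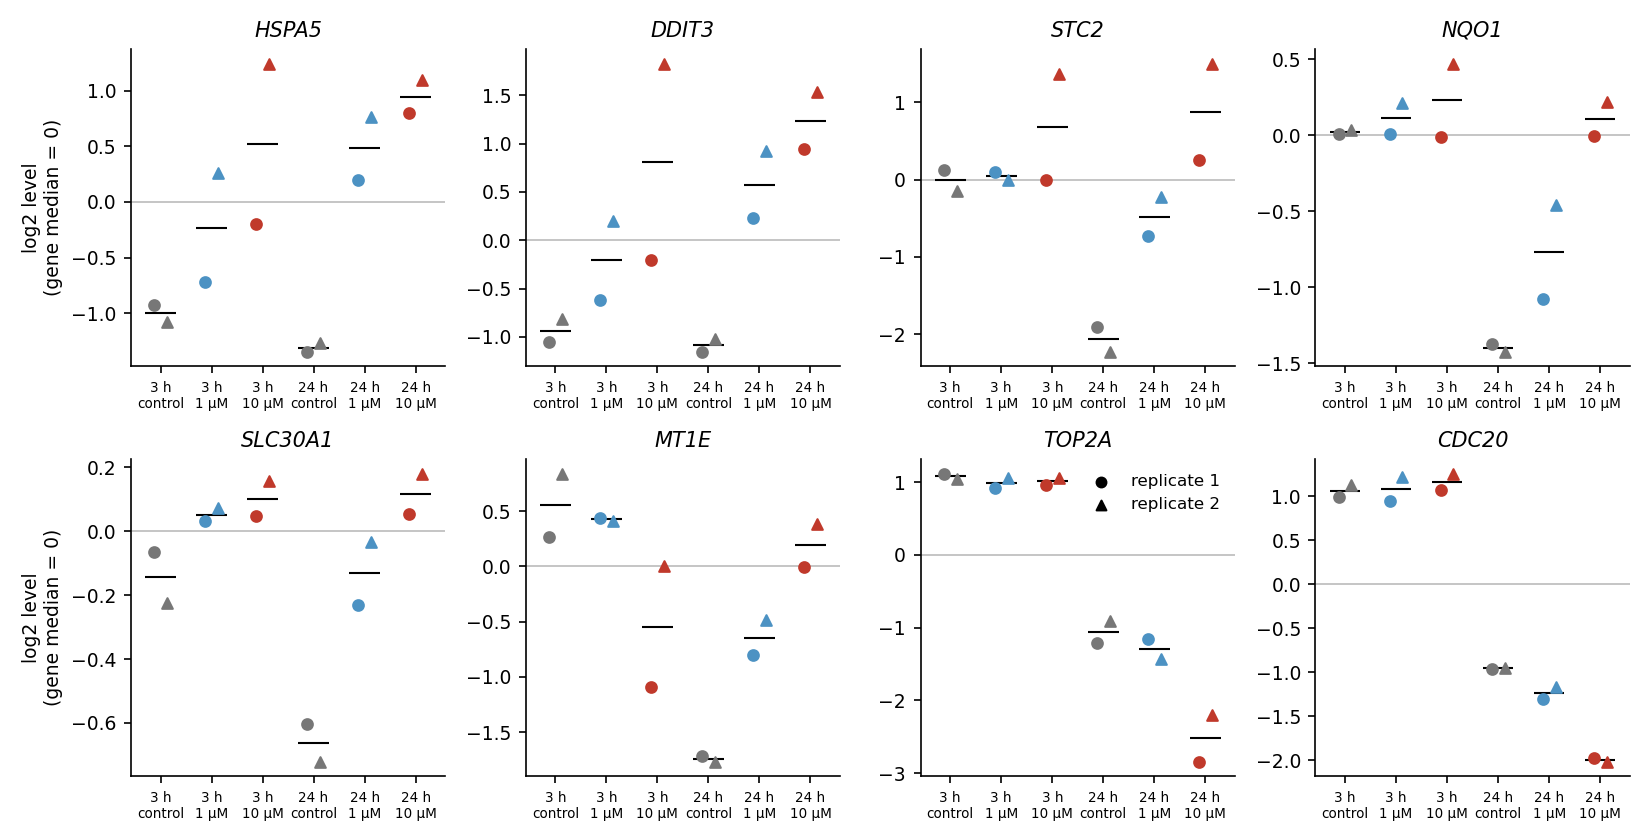
Log2 level of 8 genes in each library, relative to the gene's median over the 12 libraries. Circles are replicate 1, triangles replicate 2, and bars the mean of the 2 libraries of a group. NQO1 and SLC30A1 were low in both 24 h controls and higher in both 10 µM libraries at 24 h, and TOP2A and CDC20 were lowest there.

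A direct test of 10 against 1 µM at 24 h, whose difference holds no control library, although the controls enter its shared spread, asked whether the doses differed. All 36 cell cycle genes were lower at 10 µM, with a median of -0.42 (adjusted p = 1.86e-30, or 0.341 with an estimated correlation), and 20 passed when adjusted over the list alone. All 40 ATF4 and CHOP genes were higher, with a median of 0.49 (adjusted p = 1.59e-30, or 0.376 with an estimated correlation), and 23 passed when adjusted over the list alone. That median was 0.29 without the second 10 µM library. NRF2 genes were higher by a median of 0.15 (adjusted p = 8.85e-09, or 0.398 with an estimated correlation). ER genes were higher by 0.34 (adjusted p = 3.54e-06, or 0.753 with an estimated correlation) and cholesterol genes by 0.12 (adjusted p = 5.83e-04, or 0.753 with an estimated correlation). Both of those calls ended without the first 1 µM library, at 0.15 and 0.07. The ER median was 0.51 without the second 1 µM library and 0.22 without the second 10 µM library. Progenitor genes were lower by a median of -0.14 (adjusted p = 0.00974, or 0.376 with an estimated correlation), at -0.11 without the first 10 µM library, where the call ended, and at -0.09 without the second 1 µM library. KIF2C, at -1.37 ± 0.17, and CDC20, at -0.76 ± 0.10, did not pass, each with an adjusted p of 0.0819. Over all genes limma called 0, with 557 at an unadjusted p under 0.05, and 19 without the second 10 µM library. In a fit of the compared groups alone limma called 4. On the count table as named edgeR called 0 and DESeq2 16.

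Both doses together at 24 h gave 7 lists past the threshold against control, and of the 8 at 10 µM only the proteasome list, at -0.05 (adjusted p = 0.0660), was not among them. The ATF4 and CHOP list had a median of 0.58 (adjusted p = 2.97e-31, or 0.349 with an estimated correlation) and the ER list 0.90 (adjusted p = 4.59e-26, or 0.353 with an estimated correlation). Cell cycle genes were at -0.35 (adjusted p = 5.27e-20, or 0.349 with an estimated correlation), and at -0.19 without the second control. SLC30A1 was at 0.66 ± 0.09, SPCS2 at 0.72 ± 0.10, and ASS1, an enzyme of arginine synthesis, at 0.90 ± 0.13, all with an adjusted p of 0.0780. Limma called 0 genes, with 1453 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 11 on the count table as named. It called 146 with the replicate number as a block and 164 in a fit of the compared groups alone. The count was 185 without either 3 h library with 10 µM, 11 without the first 24 h library with 1 µM, 2 without the first 10 µM library and 7 without the second.

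The log2 differences of both doses at 24 h correlated across genes with r = 0.706, where simulated unchanged groups sharing the controls gave 0.4997. Genes are not independent replicates. The covariance was 0.0403 against 0.0178 simulated, a difference of 0.0225. All 117 genes called at 10 µM had the same sign at 1 µM, and 72 of them had an unadjusted p under 0.05 there, STC2 among them at 1.59 ± 0.47. Part of this could come from the shared controls. With each control used for 1 dose only, a split chosen after the data were seen, the correlation at 24 h was 0.359 or 0.375, depending on which control went to which dose, and simulated groups reached at most 0.0874. No gene was called at both doses. At 3 h the correlation was 0.619 against 0.499 simulated and the covariance 0.0249 against 0.0177. The simulations gave each gene 1 spread in all groups. Over all genes the 3 h controls varied more between replicates (0.157) than the 1 µM (0.121) and 10 µM (0.145) libraries. The simulated values for shared controls at 3 h can therefore be too low, and no excess is read from them. With the controls split the correlation was 0.0178 or -0.0154 at 3 h, inside the simulated range. That value covers all genes at once and says nothing of single lists. Without the second 1 µM library the correlation was 0.439 at 3 h, where simulated groups of that shape gave 0.410, and 0.499 at 24 h, where they gave 0.405.

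The comparison of 10 µM lead with control at 3 h asked what had changed early. All 25 cholesterol synthesis genes were higher, with a median of 0.37 (adjusted p = 1.91e-18, or 0.820 with an estimated correlation), and 24 passed when adjusted over the list alone. MVK, the mevalonate kinase, was at 0.61 ± 0.12 and SQLE, the squalene epoxidase, at 0.42 ± 0.11, each with an adjusted p of 0.618. The list stood at 0.24 in the first 10 µM library and 0.56 in the second. The ER list had a median of 0.73 (adjusted p = 1.76e-14, or 0.820 with an estimated correlation), and none of its genes passed when adjusted over the list alone. It stood at 0.17 without the second 10 µM library and 1.26 without the first. HSPA5 was at 1.52 ± 0.46 and the ER chaperone CALR at 1.16 ± 0.32, each with an adjusted p of 0.618.

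Smaller shifts at 10 µM and 3 h were tied to single libraries. ATF4 and CHOP genes had a median of 0.12 (adjusted p = 0.00445, or 0.820 with an estimated correlation), which was -0.06 without the second 10 µM library, 0.34 without the first, and 0.05 without the first control. Without the second control the call ended, at 0.18. Ribosomal protein genes were at -0.09 (adjusted p = 4.51e-05, or 0.820 with an estimated correlation). They were at -0.01 without the first 3 h control and -0.16 without the second, and their call ended at -0.05 when each library's trend with mean count was removed. Oxidative phosphorylation genes were at -0.05 (adjusted p = 0.0397, or 0.820 with an estimated correlation), a call that ended without the second 10 µM library, at -0.03, or the second control, at -0.06. Lysosome genes were at 0.04 (adjusted p = 0.0397, or 0.820 with an estimated correlation), a call that ended without the first control, at 0.00, or the second 10 µM library, at 0.02, and stood at 0.13 without the second control. Cell cycle genes were at -0.06 (adjusted p = 0.498). SLC30A1 was at 0.25 ± 0.10, MT2A at 1.29 ± 0.42 and MT1E at -1.10 ± 0.35, each with an adjusted p of 0.618. CYSLTR1, a leukotriene receptor gene, had the smallest p at 1.80 ± 0.24 (adjusted p = 0.302), although its value was identical in 6 of the 12 libraries, a floor that makes the difference and its SE uncertain. It was followed by CRYBA1, a lens crystallin gene with a mean of 22.9 counts, at -2.66 ± 0.39 (adjusted p = 0.336). Limma called 0 genes, with 977 at an unadjusted p under 0.05, and edgeR called 1 and DESeq2 25 on the count table as named. The count was 919 without the second control and 184 without the first 10 µM library.

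At 1 µM and 3 h cholesterol genes were again all higher, with a median of 0.25 (adjusted p = 2.71e-11, or 0.989 with an estimated correlation), and none passed when adjusted over the list alone. MVK was at 0.43 ± 0.12 (adjusted p = 0.859). The list was at 0.15 without the second 1 µM library. ER genes were at 0.25 (adjusted p = 0.00542, or 0.989 with an estimated correlation), at 0.04 without the second 1 µM library and 0.50 without the first. That call ended in the first case, and also without the second control. Ribosomal protein genes were at -0.05 (adjusted p = 0.0235, or 0.989 with an estimated correlation). They were at 0.02 without the first control, -0.14 without the second, -0.02 without the second 1 µM library and -0.10 without the first. Their call ended with the replicate number as a block and with each library's trend with mean count removed. ATF4 and CHOP genes were at 0.01 (adjusted p = 0.978). CALB1, a calcium-binding protein gene with a mean of 13.2 counts, had the smallest p, at -2.29 ± 0.38 (adjusted p = 0.859). Limma called 0 genes, with 476 at an unadjusted p under 0.05, and 602 without the second control. Counts on the table as named were 1 by edgeR and 23 by DESeq2.

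In the comparison of both doses with control at 3 h, cholesterol genes had a median of 0.32 (adjusted p = 1.20e-16, or 0.885 with an estimated correlation), and 23 of 25 passed when adjusted over the list alone. ER genes were at 0.50 (adjusted p = 1.64e-09, or 0.885 with an estimated correlation), and at 0.14 without the second 10 µM library and 0.76 without the first. Ribosomal protein genes were at -0.07 (adjusted p = 3.39e-04, or 0.959 with an estimated correlation), but at 0.00 without the first control and -0.15 without the second. SLC10A3, a gene of the bile acid transporter family, was at 0.82 ± 0.13 and ZNF90, a zinc finger gene, at -0.81 ± 0.15, both with an adjusted p of 0.617. Limma called 0 genes, with 960 at an unadjusted p under 0.05, and 1333 without the second control. On the count table as named edgeR called 1 and DESeq2 19.

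Between 10 and 1 µM at 3 h the ER list differed by a median of 0.48 (adjusted p = 3.14e-13, or 0.856 with an estimated correlation), but by -0.04 without the second 10 µM library and 0.99 without the first. Cholesterol genes differed by 0.14 (adjusted p = 4.75e-07, or 0.856 with an estimated correlation), by -0.01 without that second library and 0.29 without the first. ATF4 and CHOP genes differed by 0.12 (adjusted p = 1.61e-05, or 0.856 with an estimated correlation), by -0.06 without it and 0.34 without the first. Oxidative phosphorylation genes were at -0.03 (adjusted p = 5.16e-04), cytosolic ribosomal protein genes at -0.03 (adjusted p = 0.0230) and mitochondrial ribosomal protein genes at -0.02 (adjusted p = 0.0381). With an estimated correlation their adjusted p-values were 0.856, 0.904 and 0.856. Leaving out the first 1 µM library gave -0.02 and 0.01 for oxidative phosphorylation and cytosolic ribosomal protein genes, and leaving out the second gave -0.05 and -0.07. The mitochondrial ones were at -0.05 without the first 10 µM library and -0.01 without the second. No list passed camera without the second 10 µM library. CYSLTR1 was at 1.81 ± 0.24 and CRYBA1 at -2.81 ± 0.39, both with an adjusted p of 0.223. The number of genes called by limma was 0, with 216 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 25 on the count table as named.

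Whether the effect of lead differed between the times was tested as an interaction. For 10 µM the median difference of the ATF4 and CHOP genes was 0.63 higher at 24 h than at 3 h (adjusted p = 1.14e-19, or 0.831 with an estimated correlation), and 23 of 40 passed when adjusted over the list alone. Cell cycle genes differed by -0.51 (adjusted p = 1.84e-17, or 0.831 with an estimated correlation), with 19 of 36 past the threshold adjusted over the list alone. The latter was -0.31 without the second 24 h control. The ER median differed by 0.37 (adjusted p = 3.21e-04, or 0.831 with an estimated correlation), but by -0.08 without the first 3 h library with 10 µM and 0.87 without the second. CDC20 was at -1.14 ± 0.15 and MT1E, an uncertain gene, at 3.03 ± 0.50, both with an adjusted p of 0.2003. For 1 µM the ER genes differed by 0.49 (adjusted p = 7.24e-07), the ATF4 and CHOP genes by 0.32 (adjusted p = 2.38e-08) and the cell cycle genes by -0.13 (adjusted p = 0.0141). All had an adjusted p of 0.856 with an estimated correlation. The ER value was 0.29 without the first 3 h library with 1 µM and 0.69 without the second, and the cell cycle value was 0.01 without the second 24 h control and -0.29 without the first. Limma called 0 genes in each, with 737 at an unadjusted p under 0.05 for 1 µM and 1235 for 10 µM. Without the second 3 h control it called 370 and 556. EdgeR called 0 in each and DESeq2 14 in each on the count table as named.

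Time in the control cells, which also covers the time after replating, changed many more genes. Genes of the neuronal cytoskeleton and the synapse rose, among them DCX, a microtubule protein of young neurons, by 1.72 ± 0.10, SYN1, a synaptic vesicle protein, by 1.52 ± 0.09, and SLC17A6, a vesicular glutamate transporter, by 1.98 ± 0.15. Adjusted p-values were 5.35e-06, 6.41e-06 and 1.32e-05. The neuropeptide gene SST rose by 4.15 ± 0.59 (adjusted p = 7.58e-04). Of 38 cytoskeleton and growth cone genes 31 rose and 2 fell, with a median of 0.63 (adjusted p = 2.04e-11, or 0.158 with an estimated correlation). Of 34 synaptic genes 21 rose and 1 fell, with a median of 0.51 (adjusted p = 4.40e-07, or 0.165 with an estimated correlation). The other neuronal lists did not pass, with dopaminergic genes at 0.15 (adjusted p = 0.624) and glutamate receptor and calcium genes at 0.13 (adjusted p = 0.124). All 36 cell cycle genes fell, with a median of -1.74 (adjusted p = 2.33e-17, or 0.165 with an estimated correlation), with the cyclin gene CCNB2 at -2.07 ± 0.10 (adjusted p = 5.35e-06). The progenitor genes SOX9, at -2.64 ± 0.18 (adjusted p = 9.30e-06), and VIM, at -1.56 ± 0.12 (adjusted p = 1.43e-05), fell too.

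Other lists fell over this time too. Of 25 cholesterol genes 22 fell, with a median of -0.76 (adjusted p = 5.39e-07, or 0.404 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 72 fell, with a median of -0.40 (adjusted p = 9.41e-14, or 0.404 with an estimated correlation). Of 40 ATF4 and CHOP genes 22 fell, with a median of -0.55 (adjusted p = 5.58e-05, or 0.497 with an estimated correlation), with the serine synthesis gene PSAT1 at -1.78 ± 0.23 (adjusted p = 3.09e-04). NQO1 was at -1.42 ± 0.20 (adjusted p = 4.84e-04). Fibroblast and mesenchymal markers had a median of -0.57, with 9 of 12 lower (adjusted p = 6.09e-04, or 0.158 with an estimated correlation). The actin-binding gene CNN2 had the smallest p of all, at -3.29 ± 0.10 (adjusted p = 3.50e-07). In total 2807 genes rose and 3068 fell by limma, and 14 of 25 lists passed camera, 2 upward and 12 downward. On the count table as named edgeR called 1 gene and DESeq2 25. Of the 66 genes called higher after 10 µM lead at 24 h, 48 passed as lower over this time and 1 as higher. By direction alone only 3 of the 66 were higher. Of the 51 called lower, 43 passed as lower and 2 as higher, and 46 were lower by direction alone. Both comparisons share the 24 h controls, so the chance errors of a gene in them point in opposite directions.

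Several of the named genes lie as follows on GRCh38 in GENCODE version 29, and all are protein coding. STC2 spans 173314713 to 173329503 on chromosome 5 and SLC7A11 138164097 to 138242349 on chromosome 4, both on the minus strand. HSP90B1 spans 103930107 to 103953645 on the plus strand of chromosome 12, and DDIT3 57516588 to 57521737 on its minus strand. HSPA5 spans 125234853 to 125241330 on the minus strand of chromosome 9. SLC30A1 spans 211571568 to 211578742 on the minus strand of chromosome 1, which also holds PHGDH at 119648411 to 119744226, CDC20 at 43358955 to 43363203 and KIF2C at 44739818 to 44767767 on its plus strand. NQO1 spans 69706996 to 69726951 on the minus strand of chromosome 16, and MT1E 56625475 to 56627112 on its plus strand. TOP2A spans 40388516 to 40417950 on the minus strand of chromosome 17.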

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

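The tests of the table names, of scaling, of exchanged dose labels, of a batch in the controls and of the progenitor genes were chosen or read only after the result was seen, while the tests of mixed RNA and of the control time course were fixed before their values were seen.

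The effect of lead differed between 24 and 3 h for several lists by camera's test of the difference, none of which passed with an estimated correlation (adjusted p of 0.856 at 1 µM and 0.831 at 10 µM). At 1 µM the median difference between times was 0.49 for ER chaperone genes, 0.32 for ATF4 and CHOP genes, 0.10 for cytosolic ribosomal protein genes and -0.13 for cell cycle genes. At 10 µM it was 0.13 for NRF2 genes, 0.37 for ER genes, 0.63 for ATF4 and CHOP genes, 0.15 for ribosomal protein genes and -0.51 for cell cycle genes. Most of these values depended on single libraries. With 1 library left out, those at 1 µM ran from 0.29 to 0.69 for ER genes, 0.26 to 0.39 for ATF4 and CHOP genes, 0.02 to 0.19 for ribosomal protein genes and -0.29 to 0.01 for cell cycle genes. Those at 10 µM ran from 0.04 to 0.20 for NRF2 genes, -0.08 to 0.87 for ER genes, 0.45 to 0.83 for ATF4 and CHOP genes, 0.08 to 0.23 for ribosomal protein genes and -0.73 to -0.31 for cell cycle genes. Mitochondrially encoded genes, outside every comparison, took at least 11.3% of the counts in every column of the count table and at most 13.7%.

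The deposited tables disagree about which library a name stands for. Plain noise between processing routes argues for each count column matching its own name best, yet only 1 of 12 did, with correlations of -0.72 to 0.40 for the other 11. A count table whose columns stand in the alphabetical order of the names is consistent with all 12 of 12 columns matching that place best. That the normalized table holds the wrong names is argued against by 12 of 12 of its libraries having a nearest library of their own time, but the test is weak, since the count table under its own names scored 10. The control time comparison called 5875 genes with the normalized names and 1 by edgeR with the count names, and an exchange of names within a time stays open.

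At 3 h the ER genes were high in the second replicate of both doses (0.50 at 1 µM and 1.26 at 10 µM) and near control in the first (0.04 and 0.17). Mixed RNA from a 24 h library is argued against by a shift of 6.70% of the control time difference in the second 10 µM library, under the bound of 10 set beforehand, although the second 1 µM library reached 7.34% and the first ones 1.34% and 1.09%. Scaling is argued against by a median of 1.24 after each library's trend was removed. A batch by replicate number that reaches every well is argued against by the ER genes of the controls. Their second library differed from the first by a median of -0.0205, against 0.748 on average in the doses. The SE of 0.0444 of that control median is over the genes of the list, with 1 control library against 1. Exchanged labels between the second 1 µM and first 10 µM library changed the spread within groups by -7.15%, which the rule as first written took as fitting an exchange. That reading was changed to undecided after the value was seen. The reason was that over all genes the control, which is not exchanged, shared differences by replicate number with the 1 µM group (correlation 0.224). The doses did so with each other (0.199), and the control less with the 10 µM group (0.0877). An exchange and a difference in the timing or strength of the response to lead could therefore not be told apart by this test. At 24 h the ER genes were also higher in the second library of each dose. They stood at 0.83 against 0.55 in the first at 1 µM, and at 1.25 against 0.97 at 10 µM. An exchange at 3 h would not produce that difference.

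Cell cycle genes were lower after 10 µM lead at 24 h. A further course of normal differentiation is argued against by a slope of -0.0177 (0.0338 either way between the split controls) of other time-dependent genes, where 0.2 was needed. Scaling is argued against by a median of -0.59 after the trend was removed. A loss of progenitors as the whole cause is argued against by the median of -0.0560 for progenitor genes, against -0.57 for the cell cycle. The SE of 0.0955 of that progenitor median is over the genes of the list, which are not independent, and not over libraries. Progenitor genes were at -0.13 in each 10 µM library and -0.14 lower than at 1 µM (adjusted p = 0.00974), with NES at -0.54, so a smaller loss stays open. An effect of lead on division remains a hypothesis found and tested on the same data, and a loss of dividing cells alone stays open.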

How the results depend on the processing

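Splitting the controls, centring, removing the trend with mean count and the edgeR TMM runs were chosen after seeing the data, and all other alternatives were planned. No single gene named in the text reversed its direction under any alternative run on the normalized values, and 9 list values reversed by camera's direction, all with 1 library left out. In 3 further cases a list's median changed sign while camera's direction did not. All counts of genes stayed within 1.5 times of the reported one with a minimum of 50 counts, with median centring and with the trend removed. The cause was not tested for any change below, except that leaving out a library lowers the degrees of freedom and leaves an arm with a lone sample, assumed to vary like the other groups.

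With no low-count filter, which adds genes to the adjustment, 10 µM against control called 1 gene at 3 h and 30 at 24 h, 28 of them among the 117. It called 3 at 1 µM and 24 h, 2 for both doses at 24 h, 1 for 10 against 1 µM at 3 h, and 2 and 3 for the change over time of 1 and 10 µM. For the overlap of the 2 doses at each time, 24 h, the correlation was 0.577, where simulated unchanged groups gave at most 0.533. At 3 h it was 0.525, inside the simulated range, which reached 0.535. With only the groups compared, 24 h gave 1 gene at 1 µM, 371 at 10 µM, 164 for both doses and 4 between doses. Camera calls of lists also ended under settings that keep every library. No filter ended those of cytosolic and mitochondrial ribosomal protein genes between doses at 3 h, and a minimum of 50 counts that of lysosome genes at 10 µM and 3 h. The fit of only the groups compared ended those of lysosome genes at 10 µM and 3 h, proteasome genes at 10 µM and 24 h and mitochondrial ribosomal protein genes between doses at 3 h. Removing the trend ended those of lysosome and proteasome genes in the same comparisons, and those of cytosolic ribosomal protein genes at each dose, for both doses and between doses at 3 h and at 1 µM and 24 h.

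With the replicate block, 24 h gave 299 genes at 10 µM, among them all 117, with 146 for both doses, 3 between doses and 5 for the change over time of 10 µM. It also ended the camera calls of cytosolic ribosomal protein genes at 1 µM and 3 h (median -0.05) and of mitochondrial ribosomal protein genes between doses at 3 h (-0.02). Half-differences of the groups correlated by number at -0.0288 to 0.224 and 4 of 15 pairs of groups exceeded 0.1. Over all genes any pairing was therefore weak, and strongest between 3 h groups. This does not describe single lists, as the ER list was higher in the second library of each dose at both times.

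On the count table by its own, conflicting names, edgeR with TMM, with RLE and with upper-quartile factors each called 1 gene at 1 µM and 3 h, 1 at 10 µM and 3 h, 1 for both doses at 3 h, 0 at 10 µM and 24 h and 1 over control time. Upper-quartile factors also gave 1 for the change over time of 1 µM. DESeq2 called 23 genes at 1 µM and 3 h, 25 at 10 µM and 3 h, 15 at 1 µM and 24 h, 17 at 10 µM and 24 h, 19 and 11 for both doses at 3 and 24 h, 25 and 16 between doses at 3 and 24 h, 14 and 14 for the changes over time, and 25 over control time. If the normalized names are right, the groups in these runs hold libraries of the wrong time, and their counts do not test the comparisons named. RLE and upper-quartile factors and DESeq2 were planned for single genes, lists and the correlation of doses as well. They were not run for them, because the names conflict. The planned log2(value + 1) run was not needed, as the normalized values are on a log scale already and are the ones reported.

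With an estimated correlation camera called 0 lists in every comparison. Fry called 3 lists at 10 µM and 24 h (ATF4 and CHOP, cell cycle, and zinc, copper and iron), 22 over control time and 0 elsewhere.

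With 1 library left out at a time, numbers of genes ran as follows. At 3 h they were 0 to 602 at 1 µM, 0 to 919 at 10 µM, 0 to 1333 for both doses and 0 to 1 between doses. At 24 h they were 0 to 0 at 1 µM, 0 to 319 at 10 µM, 0 to 185 for both doses and 0 to 19 between doses. The change over time ran from 0 to 370 at 1 µM and 0 to 556 at 10 µM, and control time from 4201 to 6377. Numbers of lists were 1 to 3 at 1 µM and 3 to 8 at 10 µM at 3 h, 5 to 9 and 7 to 10 at 24 h, 2 to 6 and 7 to 10 for both doses at 3 and 24 h, and 0 to 7 and 6 to 9 between doses. They were 2 to 4 and 4 to 7 for the changes over time and 14 to 15 over control time. The correlation of doses ran from 0.439 to 0.818 at 3 h, highest without the second control, and from 0.499 to 0.760 at 24 h, highest without the first control. Simulated unchanged groups of the same shape gave 0.410 and 0.669 for the ends at 3 h and 0.405 and 0.663 for those at 24 h. With the controls split between the doses the correlation was 0.0178 or -0.0154 at 3 h and 0.359 or 0.375 at 24 h, against simulated values near 0.

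List medians that reversed are given with both ends of their range. Those of ribosomal protein genes ran from -0.135 to 0.0210 at 1 µM and 3 h and from -0.155 to 0.00246 for both doses at 3 h, lowest without the second 3 h control and highest without the first. They ran from -0.0308 without the second to 0.131 without the first 1 µM library at 1 µM and 24 h, and from -0.0683 without the second to 0.00897 without the first 1 µM library between doses at 3 h. Without the second 3 h library with 10 µM and without the first, ATF4 and CHOP genes were at -0.0595 and 0.345 at 10 µM, and between doses at -0.0616 and 0.338. Between doses the same libraries gave -0.0363 and 0.986 for ER genes and -0.0123 and 0.292 for cholesterol genes. The change over time of ER genes at 10 µM was 0.866 without the second and -0.0785 without the first. The medians that changed sign without a change in camera's direction were those of list lysosome and autophagy, lead 10 uM against control at 3 h (-0.00243 without the first 3 h control), list cell cycle, lead 1 uM effect at 24 h minus at 3 h (0.00997 without the second 24 h control), and list cytosolic ribosomal proteins, lead 10 uM against 1 uM at 3 h (0.00315 with the trend removed).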

Other observations

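The tests on the secretory lists and the synthetases were fixed before their values were seen, on lists chosen after single genes had been seen, and the test against the 3 h controls was chosen after the result was seen.

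Beyond the chaperones, the machinery that adds sugars to new proteins in the ER was higher after lead at 24 h. The oligosaccharyltransferase list had 13 measured genes, among them MLEC, an ER lectin rather than a subunit. At 10 µM 12 were higher, with a median of 0.51 (camera adjusted p = 7.26e-08, or 0.385 with an estimated correlation). At 1 µM the median was 0.32 (adjusted p = 2.56e-07, or 0.436). Over all genes 0 members passed at 10 µM. Their values there ran from -0.05 for OST4 to 1.197 for MAGT1, with MLEC at 1.06 and KRTCAP2, TUSC3 and DAD1 at only 0.02, 0.08 and 0.17. RPN1 and MAGT1, chosen after their values were seen, did not pass. RPN1 was at 1.04 ± 0.23 and MAGT1 at 1.197 ± 0.350 (limma adjusted p of 0.0871 and 0.173, n = 2 per group). A list of the signal recognition particle, its receptor and partners at the ER membrane had a median of 0.16 (adjusted p = 0.0333), although the 6 genes of the particle itself ran only from -0.08 to 0.18. The COPI coat had 0.10 (adjusted p = 0.0420) and the COPII coat 0.14 (adjusted p = 0.0674), each with 0.467 under an estimated correlation. At 1 µM the signal recognition list passed (adjusted p = 0.0307) and the COPI and COPII lists did not (0.124 for each), so 2 of these 4 lists passed there. The hypothesis that the rise extends to secretory genes outside the fixed lists predicted at least 3 of these 4 lists past the threshold, and 3 passed. The result fits a wider secretory response, but it rests on the preset correlation and on adjustment among the later lists alone. The COPI coat, nearest the threshold of those that passed, had an unadjusted camera p of 0.0180. Adjustment together with the fixed lists was not made, so whether it would still pass there was not tested. The rise was not limited to 24 h. At 10 µM and 3 h the oligosaccharyltransferase list had a median of 0.24 (camera adjusted p = 0.00260). The COPII coat had 0.13 (adjusted p = 7.51e-04) and the COPI coat 0.18 (adjusted p = 0.00340), each of these lists with 0.459 under an estimated correlation. The signal recognition list did not pass (0.571). At 1 µM and 3 h the lowest adjusted p of the secretory lists was 0.265.

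The aminoacyl-tRNA synthetases did not move as a class. Of 8 measured cytosolic synthetases off the ATF4 list 6 were lower at 10 µM and 24 h, with a median of -0.0916 (camera adjusted p = 0.139), against 0.72 ± 0.11 for GARS, which is on it. A hypothesis that all cytosolic synthetases rise alike needed at least 0.4. Mitochondrial synthetases had a median of -0.05 over 16 genes (adjusted p = 0.179), and HARS2, chosen after its values were seen, fell, at -0.30 ± 0.05 (limma adjusted p = 0.0391, n = 2 per group). Of 26 Notch pathway genes off the progenitor list only LFNG passed, at -1.66, and the median was 0.02 (adjusted p = 0.593).

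Several lists that rose after lead had fallen over control time, so lead could simply hold them at the level of the 3 h controls. Against those controls the 24 h libraries with 10 µM stood at a median of 0.26 for ATF4 and CHOP genes, with 27 of 40 above, and at -0.33 for cholesterol genes, with 5 of 25 above. The cholesterol genes lay below the 3 h level by more than 0.2 in both libraries (-0.38 and -0.27), which argues against a hold at that level for them. The ATF4 and CHOP genes lay at 0.08 in the first library and 0.43 in the second, so for them it stays open. The test first used the mean of both libraries, which argued against a hold for both lists. It was changed to single libraries after its values were seen. NRF2 genes and metallothioneins were not tested against the 3 h level as lists.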
